A study of Homo sapiens with 8 samples.

How the data were processed

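Total RNA of CCRF-CEM-C7-14 cells was labelled with biotin and hybridised to 8 single-colour oligonucleotide arrays of 54675 probe sets. Per the labels' protocols, cells were moved to medium with charcoal-stripped serum, which is low in steroid hormones, before 1 µM dexamethasone was added for 0, 2 or 10 h. The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with RMA, whose version is not given in the sources used here. RMA is known to correct background, to quantile-normalize probes and to summarise them by median polish. Whether the 8 arrays were processed together is not given in the sources used here, and array medians between 4.68 and 5.01 show that the deposited columns do not share a single distribution. The values were not centred per gene. Values of different probe sets are not on a common scale. They were set against each other to pick a probe set per gene, to average probe sets, to filter dim genes and to judge background.

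Groups came from the time stated for each array: 3 at 0 h, 3 at 2 h and 2 at 10 h. No pair of arrays had more than 0.269% identical values, so none was treated as a copy of another. Probe sets were named from the platform annotation supplied with the table: 41091 had 1 gene symbol, 1801 had several, 11721 had none and 62 were controls. Entrez identifiers of 41037 probe sets matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. Coordinates are not used here, because no genome build is named in the sources. Each gene was represented by the probe set of that single symbol with the highest mean over all 8 arrays, which left 19775 genes, 10523 of them with over 1 probe set. The treated arrays enter that mean, so the choice favours a probe set that rises over another that does not. No filter on dim probe sets was applied.

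The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per time, contrasts, eBayes), all 8 arrays in a single fit so that the groups shared an estimate of the spread, with 5 residual degrees of freedom. The 3 comparisons were 2 h against 0 h, 10 h against 0 h and 10 h against 2 h, and a moderated F test covered any time. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes, and log2 fold changes carry the moderated standard error. All adjusted p-values in the text are two-sided and come from limma unless another test is named.

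Gene lists, 30 in number with 875 entries and 815 distinct genes, of which 748 were measured, were written from general knowledge before the data were examined, as were the rule for naming genes and the alternatives below unless stated. They cover genes raised by glucocorticoids, the receptor complex, the BCL2, AP-1 and ETS families, caspases and apoptosis execution, MYC and ribosome biogenesis, G1/S and replication, G2/M, cell cycle inhibitors and quiescence, and replication histones. Others cover glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid stress, the unfolded protein response, heat shock, p53 targets, autophagy, NF-κB, Notch targets, T-lineage identity, interferon response, immediate early genes, the clock, and markers of B, myeloid, natural killer, erythroid, and epithelial and stromal cells. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a comparison. Camera asks whether a list's genes stand apart from the other genes. The test was repeated with an estimated correlation, with which none of the 30 lists passed in any comparison. Fry was also run; it asks whether a list's genes move on balance one way, or in either direction in its mixed form, without comparing them with other genes.

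The genes named in the text were chosen by rule. For each comparison with 0 h these were the 7 largest rises and the 7 largest falls among called genes whose arrays did not overlap between the times, and 5 and 5 for 10 h against 2 h. For each list that passed camera or held at least 3 called members, up to 4 called members with the smallest adjusted p were added. A fixed panel was given whatever its result: NR3C1, TSC22D3, FKBP5, BCL2L11, BMF, BCL2, MCL1, BCL2L1, ERG, JUN, FOS, MYC, CCND3, CDK6, DUSP1, PER1, ZBTB16, IL7R, TXNIP, NOTCH1 and RAG1. The PER1 probe set carries several symbols, so PER1 was not analysed here. Any gene named outside this rule is said to have been chosen after its values were seen.

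The 27 Bacillus probe sets served as negative controls and ran from 1.52 to 4.73. A gene whose untreated mean did not exceed 4.73 was taken to be at background. RNA integrity was read from 3-prime and 5-prime control probe sets of actin and GAPDH, compared between times by an exact permutation test. No pooled correlation of array measures with the first component is given, because the arrays fall into a set of 3 and a set of 5; differences between the sets were tested by exact permutation instead, a choice made after the pooled values had been seen.

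The steps were tested on simulated data with 200 changed genes among 19775 in 10 runs per comparison. At a log2 change of 1 the fit recovered 89.3% of changed genes for 2 h against 0 h, 77.8% for 10 h against 0 h and 77.5% for 10 h against 2 h. At a log2 change of 0.5 it recovered 7.91%, 5.67% and 6.27%, so changes of that size were mostly not detectable with these arrays. False calls numbered 11.0, 9.9 and 10.6 per run. With 200 changed genes planted, a smaller change can pass the adjusted threshold than where few genes change. At 2 h against 0 h in the real arrays 4 genes were called, the smallest at a log2 fold change of 1.85. The recovered shares and false calls therefore do not carry over to that comparison. A list shifted by −0.3 was found in 10 of 10 runs at 10 h against 0 h and 0 of 290 other lists were called. The simulated genes varied independently of each other. These runs therefore cannot show how often a list of correlated genes would be called falsely.

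The alternatives were the mean of all probe sets, each probe set tested, a preference for probe sets without a cross-hybridization suffix (those not ending in _s_at, _x_at or _a_at), median centring, quantile normalization, filters at the median gene and at a mean of 5, trended robust variances, array weights, only the arrays of the groups compared, a block for the replicate number, a threshold of 0.01, a threshold of at least 2-fold, and leaving out each array in turn. When an array of 10 h is left out, the lone remaining array is assumed to vary like the other groups. Alternatives chosen after seeing the data were a block for the 3 arrays with the lowest medians, the array median as a covariate, and leaving those 3 arrays out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.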

Results

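CCRF-CEM-C7-14 is a human T-cell acute lymphoblastic leukaemia line that responds to glucocorticoids. Dexamethasone is a synthetic glucocorticoid that binds the glucocorticoid receptor, the product of NR3C1, and turns it into a DNA-binding transcription factor. Total RNA was measured on 8 expression arrays: 3 from untreated cells at 0 h, 3 after 2 h and 2 after 10 h in 1 µM dexamethasone. The arrays of a time are labelled as biological replicates, and nothing further says how separate the cultures were, so p-values measure the spread between these samples. No vehicle-treated arrays at 2 h or 10 h were used here, so the hormone and the time in hormone-stripped medium varied together. The number of arrays, 2 to 3 per time, limits the precision of every value.

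Values were log2 expression, between 1.35 and 13.9, and array medians lay between 4.68 and 5.01. Any pair of arrays correlated at 0.985 to 0.995 across genes, with 0.987 to 0.995 between arrays of the same time. The first principal component held 35.9% of the variance between arrays and did not follow time. It set 0 h replicate 2, 2 h replicate 3 and 10 h replicate 1, the 3 arrays with the lowest medians, apart from the other 5. The difference between 3-prime and 5-prime control probe sets, a measure of RNA integrity, did not separate the times in an exact permutation test over 560 assignments. For actin it was 0.52 ± 0.18 (SD, n = 3) at 0 h, 0.51 ± 0.11 (SD, n = 3) at 2 h and 0.33 ± 0.05 (SD, n = 2) at 10 h (exact p = 0.318, adjusted p = 0.979). For GAPDH it was 0.21 ± 0.03, 0.24 ± 0.12 and 0.13 ± 0.15 at the same times (exact p = 0.529, adjusted p = 0.979).

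The first comparison asked which transcripts had moved after 2 h of hormone. In limma, 4 of 19775 genes rose and none fell at a Benjamini-Hochberg adjusted p below 0.05, and at an unadjusted p below 0.05, 126 rose and 61 fell. With array weights 24 genes rose and 2 fell. TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, went from 5.64 ± 0.15 (SD, n = 3) to 8.42 ± 0.27 (SD, n = 3), a log2 fold change of 2.78 ± 0.19 (SE) or 6.85-fold (adjusted p = 1.35e-06). RUNX2, a Runt-family transcription factor, rose by 2.72 ± 0.25 (SE; adjusted p = 4.45e-05). TNFSF8, the CD30 ligand, rose by 1.90 ± 0.23 (SE; adjusted p = 0.0011), and BTG1, an antiproliferative factor, by 1.85 ± 0.21 (SE; adjusted p = 0.0005). For each of the 4 genes, all 3 arrays at 2 h lay above all 3 arrays at 0 h, an arrangement that 4.04% of all genes showed in either direction and that chance gives for 10%.

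Among the other genes fixed for naming, none passed at 2 h. NR3C1 itself had a log2 fold change of 1.03 ± 0.21 (SE; adjusted p = 0.293), with all 3 arrays above the untreated arrays. It was called without 2 h replicate 3, with trended robust variances, with array weights, and with the block or the covariate for array medians, and FKBP5 was called with trended robust variances and array weights. FKBP5, a co-chaperone of the receptor, had 0.72 ± 0.19, IL7R, the interleukin 7 receptor chain, 0.48 ± 0.22, and BCL2L11, the pro-apoptotic protein BIM, 0.43 ± 0.19, each at an adjusted p of 1.00. JUN was at 0.11 ± 0.21, MYC at −0.12 ± 0.18, TXNIP at −0.07 ± 0.21 and NOTCH1 at −0.06 ± 0.19. BCL2 was at −0.18 ± 0.22, BMF at 0.10 ± 0.17, MCL1 at 0.03 ± 0.17, BCL2L1 at 0.02 ± 0.19 and DUSP1 at 0.08 ± 0.23. CCND3 was at 0.08 ± 0.18, CDK6 at 0.12 ± 0.17, RAG1 at 0.08 ± 0.51, and ERG, FOS and ZBTB16, all at the level of negative controls, between −0.12 and 0.03.

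Genes long known to be raised by glucocorticoids were shifted upwards as a list at 2 h. Of its 57 measured members, 38 had a positive log2 fold change, 2 were called over all genes and 9 when adjusted over the list alone. Their mean log2 fold change was 0.27 and their median 0.08 (camera, up, adjusted p = 1.92e-09; adjusted p = 0.991 with an estimated correlation). The receptor and its chaperones and cofactors also passed, with 20 of 24 members positive and a mean of 0.16 (camera, up, adjusted p = 0.0039; adjusted p = 0.991 with an estimated correlation). None of these 24 genes was called over all genes and 2 were when adjusted over the list alone. The other 28 lists did not pass at 2 h. At an unadjusted p below 0.05, 187 genes were found where 989 would be by chance, and 529 with a block for the 3 arrays with the lowest medians, a setting chosen after seeing the data.

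The count of 4 depended on how probe sets and arrays were handled. It was 1 when all probe sets of a gene were averaged, 2 when probe sets without a cross-hybridization suffix were preferred, 7 without 2 h replicate 3, and 8 with a block for the 3 arrays with the lowest medians, a setting chosen after seeing the data. TSC22D3, RUNX2 and TNFSF8 lost their calls when probe sets were averaged, and BTG1, then at 0.40, when probe sets without the suffix were preferred. Of the 3 probe sets of TSC22D3, the brightest over all 8 arrays gave the 2.78, and its own rise adds to that brightness. The single TSC22D3 probe set without such a suffix had −0.11, and the lowest of the 6 RUNX2 probe sets −0.35. Their means of 4.45 and 3.39 lay below the highest negative control value of 4.73, and so did the BTG1 probe set without the suffix, at 4.19. Other uncalled probe sets lay above that value. TSC22D3 had 0.62 on a probe set with a mean of 6.79, and RUNX2 had 0.13, 0.14 and 0.16 on probe sets with means of 5.52, 5.06 and 4.82. The rise of RUNX2 at 2 h thus rested on 1 probe set of 6, and that of TSC22D3 was called on 1 of 3. TNFSF8 was also called on 1 of 3, and its other probe sets had 0.84 and 0.54 at means of 6.27 and 5.45.

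**Figure D1:**
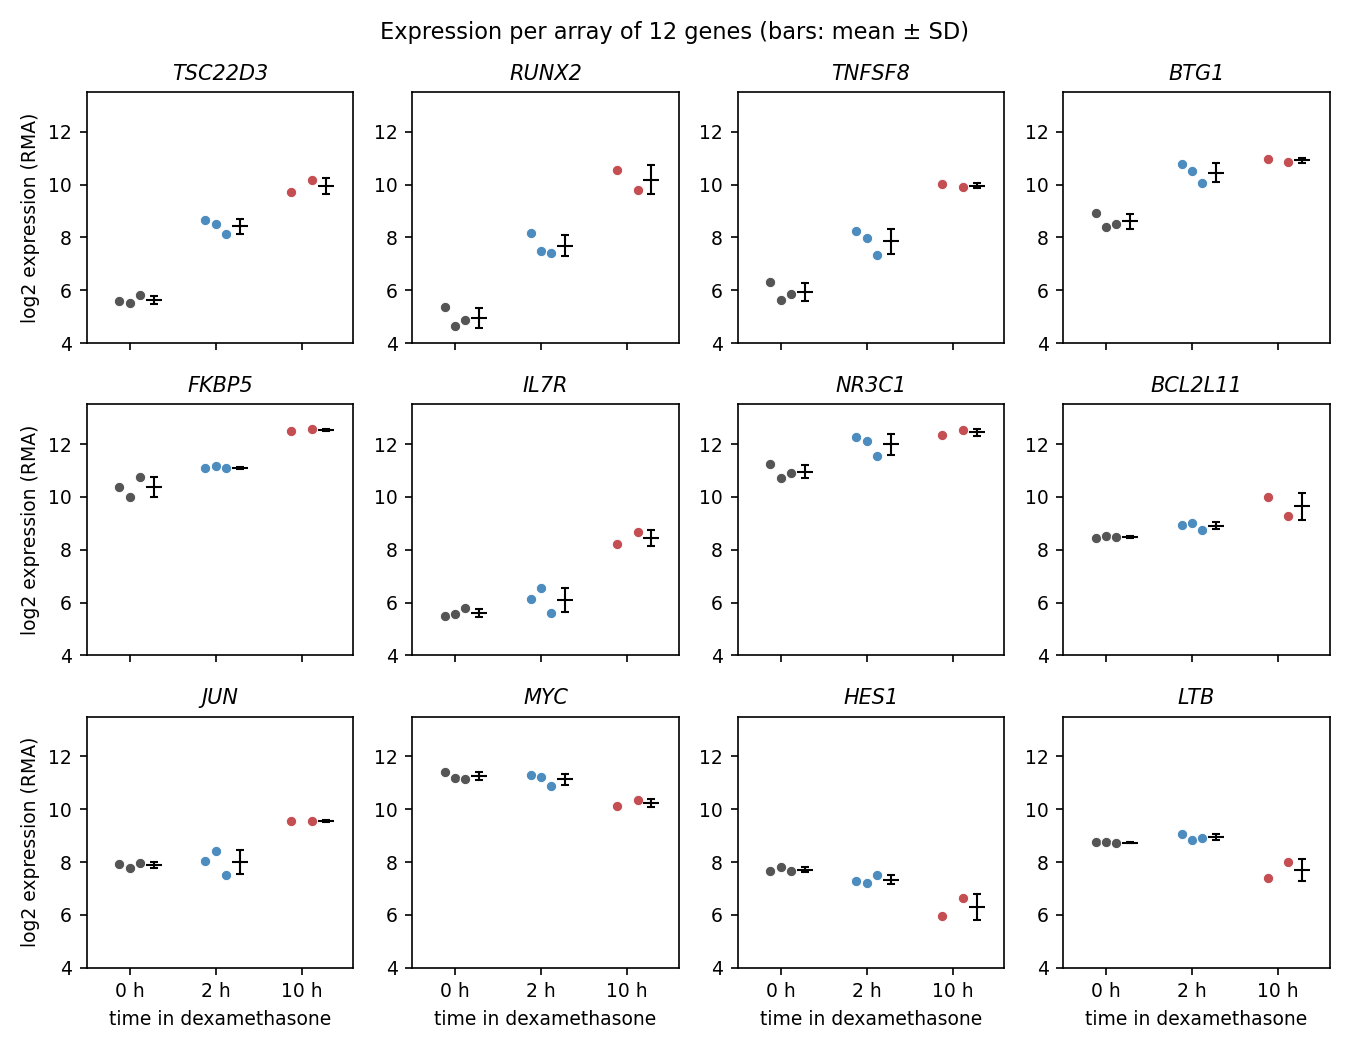
Log2 expression (y axis, RMA values) of 12 genes at 0 h, 2 h and 10 h of dexamethasone (x axis). Each point is an array (3, 3 and 2 per time) and the bar beside it gives the mean and SD. TSC22D3 rises from 5.64 to 8.42 and 9.94, while MYC falls from 11.2 to 10.2 between 0 h and 10 h.

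After 10 h, 70 genes differed from 0 h: 66 rose and 4 fell. At an unadjusted p below 0.05, 426 rose and 255 fell, 681 in all where 989 would be by chance. With a block for the 3 arrays with the lowest medians, a setting chosen after seeing the data, 1316 genes were below 0.05. RUNX2 had the largest change, from 4.97 ± 0.38 (SD, n = 3) to 10.2 ± 0.55 (SD, n = 2), a log2 fold change of 5.21 ± 0.28 (SE), or 37.1-fold with a 95% interval of 24.7 to 55.8 (adjusted p = 9.79e-09). TSC22D3 rose by 4.30 ± 0.22 (SE; 19.7-fold, adjusted p = 7.22e-09) and TNFSF8 by 4.01 ± 0.26 (SE; 16.1-fold, adjusted p = 1.10e-07). TRIB1, a pseudokinase, rose by 3.79 ± 0.34, the non-coding RNA LINC01120 by 3.11 ± 0.26, IL7R by 2.83 ± 0.25 and MACROD2, an ADP-ribosyl hydrolase, by 2.67 ± 0.27. TRIB1 and LINC01120 started at 3.55 and 4.71, below the highest negative control value of 4.73. Of their probe sets, 1 of 3 for TRIB1, 1 of 2 for LINC01120 and 2 of 4 for MACROD2 were called. The lowest values were −0.23, 0.09 and −0.14, and every uncalled probe set of these 3 genes had a mean below 4.73. So did the called MACROD2 probe set that gave 3.27, at a mean of 4.16. With averaged probe sets the rises were 1.35, 1.60 and 1.45, and all 3 stayed called. RUNX2 then had 1.64 and stayed called, below the 3.23 of TNFSF8, so its rank as the largest change rests on the probe set chosen. All 70 genes changed by at least 2-fold, 18 by at least 4-fold, and for all 70 the arrays of the 2 times did not overlap, which chance gives for 20% of genes and 13.1% of all genes showed.

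The 4 genes that fell were HES1, APLN, LTB and MYC. HES1, a Notch-responsive repressor, fell by 1.42 (log2; SE 0.22, adjusted p = 0.0030). APLN, the peptide hormone apelin, fell by 1.25 (SE 0.21, adjusted p = 0.0055), and LTB, lymphotoxin beta, fell by 1.04 (SE 0.21, adjusted p = 0.0293). Each of these 2 genes was called on 1 of 2 probe sets. The other had −0.04 for APLN and −0.13 for LTB, at means of 5.19 and 5.34, above the negative controls. MYC, a growth-promoting transcription factor, fell by 1.01 (SE 0.20, adjusted p = 0.0300), from 11.2 ± 0.14 (SD, n = 3) to 10.2 ± 0.15 (SD, n = 2). MYC stayed past the threshold in 16 of 22 alternatives and LTB in 14 of 22. Both were lost without 0 h replicate 1, 0 h replicate 2, 2 h replicate 2 or 10 h replicate 1 in turn, and MYC also without 10 h replicate 2. LTB and APLN were also lost with averaged probe sets, LTB and HES1 with the suffix preference, and LTB with a replicate block. Without the 3 arrays with the lowest medians, a setting chosen after seeing the data, MYC, LTB and HES1 lost their calls. Over all 22 alternatives the log2 fold change of MYC stayed between −1.12 and −0.90, that of LTB between −1.32 and −0.13, that of HES1 between −1.77 and −0.37 and that of APLN between −1.50 and −0.65.

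The glucocorticoid-induced list rose most. Of 57 members, 17 were called over all genes and 22 when adjusted over the list alone, all raised, with a mean log2 fold change of 0.69 and a median of 0.34 (camera, up, adjusted p = 4.10e-36; adjusted p = 0.385 with an estimated correlation). Besides TSC22D3 and IL7R, its called members included ISG20, an interferon-inducible exonuclease, at 2.50 ± 0.22 (SE; adjusted p = 6.48e-06) and BTG1 at 2.31 ± 0.23 (SE; adjusted p = 3.29e-05). FKBP5 rose by 2.16 ± 0.22 (SE; adjusted p = 3.67e-05), TXNIP, an inhibitor of thioredoxin and of glucose uptake, by 1.43 ± 0.23 (SE; adjusted p = 0.0045), and NR3C1 by 1.49 ± 0.23 (SE; adjusted p = 0.0037). The receptor complex list held FKBP5 and NR3C1 as its 2 called members, and 13 of its 24 members had negative values (camera adjusted p = 0.288).

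In the BCL2 family, 1 of 19 genes was called at 10 h. BCL2L11 rose by 1.16 ± 0.22 (SE; adjusted p = 0.0183), and 6 of its 7 probe sets were called, with log2 fold changes over the 7 from 0.14 to 2.39. BCL2 had −0.42 with a 95% interval of −0.94 to 0.10, MCL1 0.07 (−0.33 to 0.46), BCL2L1 −0.05 (−0.48 to 0.39) and BMF −0.08 (−0.49 to 0.32), none of which passed. The family did not pass as a list (camera adjusted p = 0.276).

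JUN, a component of the AP-1 transcription factor, was the only called member among 16 AP-1 family genes, at 1.67 ± 0.23 (SE; adjusted p = 0.0010). 3 of its 4 probe sets were called and the other had 0.83. FOS had 0.16 ± 0.22 at an untreated level of 3.67, and the AP-1 list did not pass (camera adjusted p = 0.276). Among 21 ETS family genes none was called (camera adjusted p = 0.935). ERG had −0.51 ± 0.41 from an untreated level of 4.70, within the range of the negative controls.

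Lists tied to growth and DNA replication were shifted downwards at 10 h. Of 48 genes of MYC activity and ribosome biogenesis, 41 had negative values with a mean of −0.24, and MYC was the only called member over all genes and over the list alone (camera, down, adjusted p = 5.18e-09; adjusted p = 0.907 with an estimated correlation). The mean of this list was −0.36 within the 3 arrays with the lowest medians and −0.11 within the other 5. Of 54 genes of the G1/S transition and DNA replication, 43 had negative values with a mean of −0.17 and none was called (camera, down, adjusted p = 2.32e-05; adjusted p = 0.907 with an estimated correlation). Among the cell cycle genes of the panel, CCND3 had −0.08 ± 0.20 and CDK6 0.10 ± 0.19.

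3 further lists were shifted upwards. For interferon response genes, 21 of 29 had positive values with a mean of 0.28, which was 0.40 within the 3 arrays with the lowest medians and 0.23 within the other 5. ISG20 was the only member called over all genes and 3 were when adjusted over the list alone (camera, up, adjusted p = 8.50e-06; adjusted p = 0.907 with an estimated correlation). Of 20 cell cycle inhibitors and quiescence genes, BTG1 and KLF2, a quiescence-associated transcription factor, were called, 10 values were positive and 10 negative (camera, up, adjusted p = 0.0130; adjusted p = 0.907 with an estimated correlation). KLF2 rose by 1.18 ± 0.22 (SE; adjusted p = 0.0217), and its other probe set, at a mean of 4.42 within the range of the negative controls, had −0.22. Of 34 autophagy and lysosome genes 24 were positive, with a mean of 0.11 and none called (camera, up, adjusted p = 0.0135; adjusted p = 0.907 with an estimated correlation).

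Some lists held called genes of both directions and did not pass as a whole. Among 18 Notch targets, IL7R rose while HES1 and MYC fell (camera adjusted p = 0.390). NOTCH1 had −0.69 ± 0.21 (SE; adjusted p = 0.503). Among 28 NF-κB and inflammatory genes, CD69, an early activation antigen, rose by 1.87 ± 0.34 (SE; adjusted p = 0.0131) and NFKBIA, the NF-κB inhibitor, by 1.35 ± 0.26 (SE; adjusted p = 0.0203), while LTB fell (camera adjusted p = 0.390). The other probe set of NFKBIA, at a mean of 5.20, had −0.39. Among 27 immediate early genes, JUN and KLF2 rose and MYC fell (camera adjusted p = 0.178). DUSP1 had 0.08 ± 0.25, ZBTB16 −0.14 ± 0.20 and RAG1, a recombinase of immature lymphocytes, −0.81 ± 0.57.

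The number of genes called fell when either of the 2 arrays at 10 h was left out, and other settings moved it too. Without 10 h replicate 1, 37 genes were called, 36 of them among the 70, and without 10 h replicate 2, 35 were called, all among the 70. With a block for the 3 arrays with the lowest medians, a setting chosen after seeing the data, 110 genes were called, including all 70, and without those 3 arrays 30 were called, 29 of them among the 70. NR3C1, KLF2, NFKBIA and APLN were lost without 10 h replicate 1 and again without 10 h replicate 2, BCL2L11, CD69 and HES1 without replicate 1, and TXNIP without replicate 2. BCL2L11, KLF2 and CD69 were also lost without 0 h replicate 1. CD69 was not called after median centring, quantile normalization or with trended robust variances, BCL2L11 not after quantile normalization and NFKBIA not after median centring. The log2 fold change of CD69 was 1.90, 1.90 and 1.87 under those 3 settings, and ran from 1.41 to 2.34 over 22 alternatives. KLF2 and NFKBIA were lost with averaged probe sets, and KLF2 with a replicate block. Without the 3 arrays with the lowest medians, NR3C1, BCL2L11, TXNIP, KLF2, CD69 and NFKBIA were lost as well. Over 22 alternatives NR3C1 stayed between 1.28 and 1.85, BCL2L11 between 0.81 and 2.39 and TXNIP between 1.21 and 1.62. On probe sets without a cross-hybridization suffix TSC22D3 had −0.16, and BTG1 at 0.99 and JUN at 0.83 lost their calls. These 3 probe sets had means of 4.45, 4.19 and 4.67, below the highest negative control value of 4.73. Of the 6 RUNX2 probe sets 2 were called, with values over the 6 from −0.05 to 5.21. The lower of the 2 called, at 2.19, had a mean of 4.24, also below 4.73. The uncalled RUNX2 probe sets included 3 above the negative controls, which had −0.05, 0.97 and 1.10 at means of 5.06, 5.52 and 4.82. For TSC22D3, 2 of 3 probe sets were called, at 4.30 and 1.37.

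**Figure D2:**
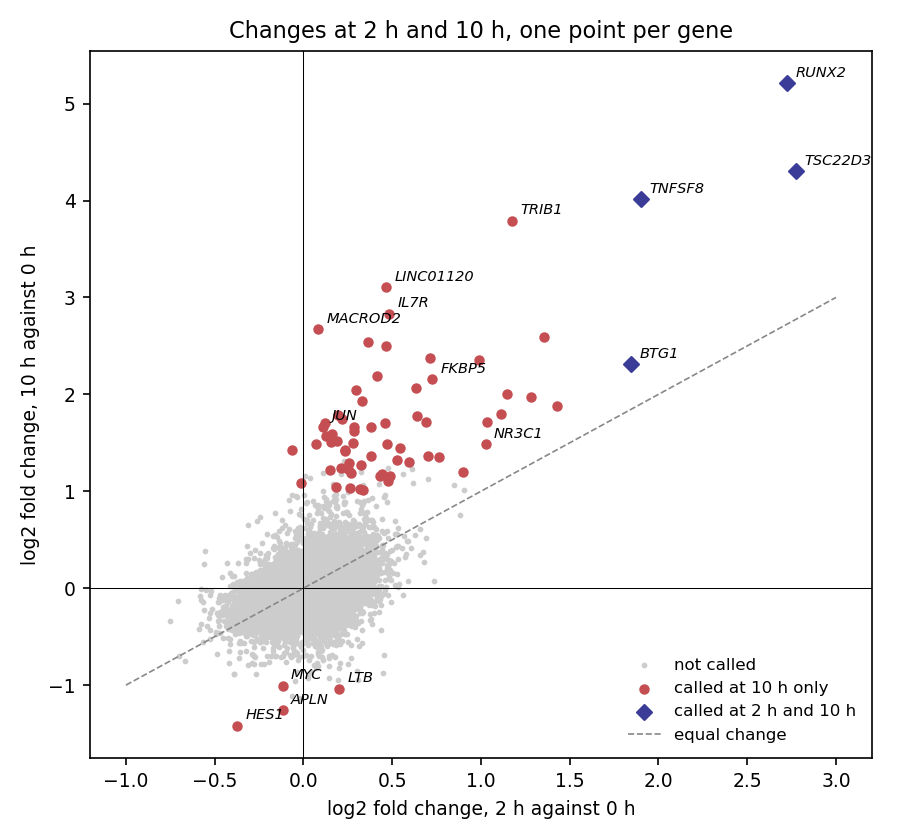
Log2 fold change at 10 h against 0 h (y axis) and at 2 h against 0 h (x axis), with a point for each of 19775 genes. Red points are the 66 genes called at 10 h and not at 2 h, blue diamonds the 4 called at both, and the dashed line marks equal change. RUNX2 lies at 2.72 and 5.21, above that line, and HES1 at −0.37 and −1.42, below it.

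All 4 genes raised at 2 h were also raised at 10 h. Independent lists of these sizes would share 0.0134 raised genes. In 100 simulations of unchanged groups, with simulated untreated arrays used in both comparisons, 0.14 calls were shared on average and 2 at most. No change was put in at 10 h, so these runs do not show the overlap that shared arrays give when 66 genes rise. Both comparisons used the same 3 untreated arrays, which are too few to split.

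The direct comparison of 10 h with 2 h asked which transcripts moved between the times. It called 33 genes, 31 higher and 2 lower at 10 h, while at an unadjusted p below 0.05 there were 272 higher and 350 lower, 622 in all where 989 would be by chance. With a block for the 3 arrays with the lowest medians, a setting chosen after seeing the data, 1177 genes were below 0.05. Of the 33 called genes, 30 were called against 0 h at 10 h and not at 2 h. TSC22D3, RUNX2 and TNFSF8 were called at 2 h and rose further. None of the 4 genes called at 2 h fell back, and rises too small to be called at 2 h could not enter this count. The largest rises were those of LINC01120 at 2.64 ± 0.26 (SE; adjusted p = 0.0002), TRIB1 at 2.62 ± 0.34, MACROD2 at 2.59 ± 0.27, RUNX2 at 2.49 ± 0.28 and IL7R at 2.35 ± 0.25. TRIB1 stood at 4.73 at 2 h, no higher than the highest negative control, so its size and rank here are taken against background. The ranks rest on the probe set chosen. With averaged probe sets LINC01120 had 1.47, TRIB1 0.95, MACROD2 1.34 and RUNX2 1.06, below the 2.68 of IL7R. The lowest single probe sets of LINC01120, TRIB1 and MACROD2 had 0.29, 0.04 and −0.09, all at means below 4.73. ISG20 rose by 2.03 ± 0.22, JUN by 1.56 ± 0.23, TSC22D3 by 1.52 ± 0.22 and FKBP5 by 1.43 ± 0.22, and TXNIP was 2.82-fold higher. LTB fell by 1.24 (SE 0.21, adjusted p = 0.0117) and APLN fell by 1.14 (SE 0.21, adjusted p = 0.0273). BTG1 had 0.46 ± 0.23, NR3C1 0.46 ± 0.23, BCL2L11 0.73 ± 0.22 and MYC −0.89 ± 0.20 (adjusted p = 0.152), none of which passed. MYC was called with quantile normalization, trended robust variances, array weights, the block and the covariate, and BCL2L11 when all its probe sets were averaged, each was tested, or those without the suffix were preferred.

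Between 2 h and 10 h, 8 lists passed. The glucocorticoid-induced list rose by a mean of 0.43, with 15 members called when adjusted over the list alone (camera adjusted p = 3.24e-25; adjusted p = 0.756 with an estimated correlation). MYC activity and ribosome biogenesis was lower by a mean log2 fold change of −0.31, with 43 of 48 members negative (adjusted p = 4.14e-14), and G1/S and replication by −0.25, with 52 of 54 negative (adjusted p = 2.19e-10). Glycolysis and glucose uptake was lower by −0.18, with 19 of 24 negative and none called (adjusted p = 0.0266). Cell cycle inhibitors and quiescence genes had a mean of 0.12 (adjusted p = 0.0140), and markers of natural killer and cytotoxic cells had 0.14 with 9 of 11 positive and none called (adjusted p = 0.0389). With an estimated correlation, the adjusted p of each of these last 5 lists was 0.760. Interferon response genes had a mean of 0.19 (adjusted p = 0.0004) and autophagy and lysosome genes 0.07 (adjusted p = 0.0389), and both were at an adjusted p = 0.948 with an estimated correlation. Several of these shifts were larger within the 3 arrays with the lowest medians than within the other 5. The means were 0.40 and 0.09 for interferon response genes, 0.35 and 0.04 for natural killer and cytotoxic markers, −0.31 and −0.08 for glycolysis, −0.37 and −0.13 for G1/S and replication, 0.20 and 0.11 for cell cycle inhibitors and 0.58 and 0.37 for the glucocorticoid-induced list. They were −0.28 and −0.25 for MYC activity and ribosome biogenesis, and 0.07 and 0.12 for autophagy and lysosome genes.

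Of the 33 genes, 13 were called without 10 h replicate 1, where 14 genes were called in all, and 12 without 10 h replicate 2, where 12 were called. FKBP5 and JUN were lost without 10 h replicate 1 and again without 10 h replicate 2, TRIB1 without replicate 1, and TSC22D3 and TXNIP without replicate 2. With averaged probe sets TSC22D3, TRIB1, LTB and APLN were lost, and with the suffix preference LTB and JUN, while TSC22D3 changed sign on a probe set at background. Without the 3 arrays with the lowest medians RUNX2 (adjusted p = 0.125, against 2.86e-07 at the lowest of its 22 alternatives), LTB, APLN, FKBP5, JUN and TXNIP were lost. LTB was lost without 2 h replicate 1 or 10 h replicate 1, and APLN without 2 h replicate 1, 2 h replicate 2, 10 h replicate 1 or 10 h replicate 2. Over 22 alternatives FKBP5 stayed between 1.40 and 1.80, JUN between 0.91 and 2.01, LTB between −1.53 and −0.0024 and APLN between −1.30 and −0.57. The block for the 3 arrays with the lowest medians gave 52, including all 33. In a single test over the 3 times, 56 genes were called at any time, 27 without 10 h replicate 1 and 23 without 10 h replicate 2.

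**Figure D3:**
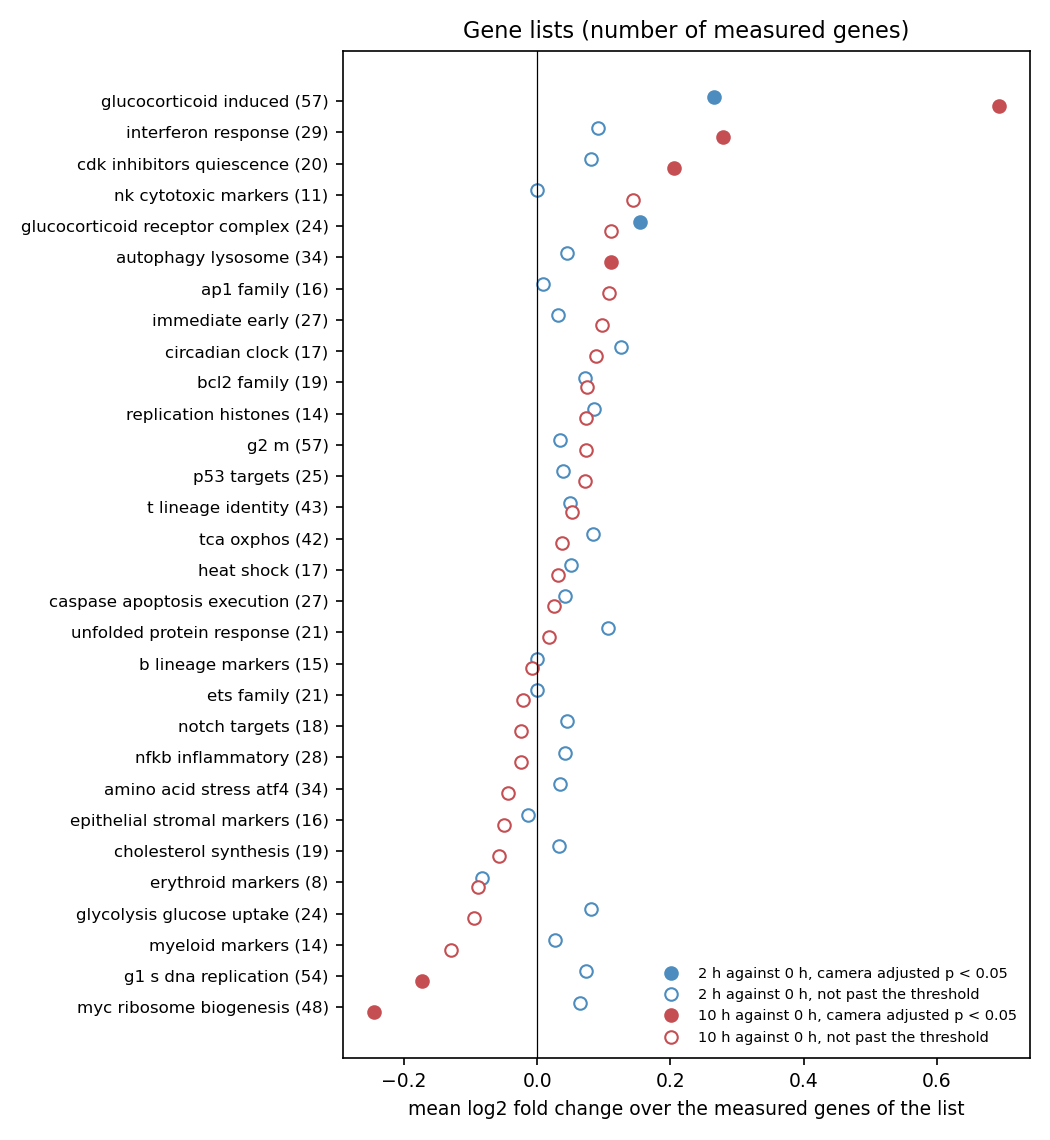
Mean log2 fold change of 30 gene lists (x axis) at 2 h against 0 h (blue) and at 10 h against 0 h (red), with the number of measured genes in brackets. Filled points passed camera with its preset correlation. The glucocorticoid-induced list stands at 0.27 and 0.69, and MYC activity and ribosome biogenesis at 0.06 and −0.24.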

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

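The tests of the array axis and of array scaling were chosen only after the result was seen.

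The direct comparison of 10 h with 2 h called 33 genes whose change differed between the times, 31 of them higher at 10 h. This is a tested difference between time points.

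The 3-prime control probe set of 18S ribosomal RNA, which enters no comparison, read 13.0 on 2 h replicate 2, above the untreated arrays, which reached 10.0 at most. Another 13522 probe sets with no gene symbol or with several were tested apart from the genes. Of these, 9 without a symbol were raised at 10 h against 0 h in limma, the largest rise being 2.35 ± 0.30 (SE, log2; adjusted p = 0.0050) and the next 2.13 ± 0.32 (SE; adjusted p = 0.0201), the latter from an untreated mean of 4.20, below the highest negative control. None of the 13522 was lowered past the threshold.

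The first component, with 35.9% of the variance, set 1 array of each time apart from the other 5. Time in dexamethasone is argued against, since it held 0.918% of this component's variance, against a median of 24.7% over 560 regroupings (exact p = 0.964). Hybridization stays open: the hybridization controls averaged −0.37 lower (log2) on the 3 arrays than on the other 5 (exact permutation p = 0.214 over 56 splits, adjusted p = 0.286 over 4 measures). RNA or labelling length also stays open, because actin's 3-prime minus 5-prime difference moved by −0.21 (exact p = 0.0714, adjusted p = 0.143) while GAPDH's moved the other way by 0.07 (exact p = 0.393). The negative controls were lower by −0.25 on the 3 arrays (exact p = 0.0179, the smallest that 56 splits can give, adjusted p = 0.0714). These arrays were picked by their low medians, which low background values go with, so this p-value is no separate evidence.

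Of the 70 genes called at 10 h, 94.3% were raised. Array scaling as the whole cause is argued against, since the share was 93.7% of 95 calls after median centring and 91.0% of 100 calls after quantile normalization. A floor near background is argued against as well, because 44 of 48 called genes above the median gene were raised, 91.7% with an exact binomial interval of 80.0% to 97.7%. That interval treats genes measured on the same arrays as independent, so it does not measure the spread between arrays. The skew was smaller under array weights, at 75.6% with 96 raised and 31 lowered, and at unadjusted p-values, with 426 raised and 255 lowered below 0.05 and 199 and 53 below 0.01. Early induction by the receptor remains as a hypothesis, since time in medium, which went with the hormone, was not tested.

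Of the 66 genes raised at 10 h, 64 already had a positive value at 2 h, with a median log2 fold change of 0.42 there and 1.61 at 10 h. Shared untreated arrays as a cause stay open. Over 100 simulations with no change at 2 h the median ran from −0.07 to 0.09 and the positive share from 36.4% to 68.7%. These simulations took the fitted 10 h changes of the called genes as true. That weakens the selection of genes with low untreated values, so they cannot decide how much the shared arrays add. A slow build-up of the hormone response is a candidate explanation for the median of 0.42, and part or all of its size may come from the shared arrays. Time in medium went with the hormone and was not tested.

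Chance as the source of the calls was examined by regrouping arrays. For 2 h against 0 h the real split of the 6 arrays gave 4 genes, the highest other split gave 2, and 1 of 10 splits reached the real count, which is too few splits for a share under 0.05. For genes changed at any time, 2 of 100 drawn splits of the 8 arrays gave as many as the real 56, the real split included. This share lies below 0.05 and argues against chance. It does not exclude chance, because 1 drawn split gave more genes than the real split and only 100 of 280 were drawn. The highest other split gave 63 and kept both 10 h arrays together with 2 h replicate 1.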

How the results depend on the processing

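The alternatives with the 3 arrays of lowest medians were chosen only after the data were seen. Signal over background limits 7 of the 66 genes raised at 10 h, whose untreated mean was at or below 4.73. Genes changed at 2 h numbered 4 in limma under median centring, quantile normalization, both dim-gene filters, each probe set tested and both other thresholds. They numbered 1 with the mean of all probe sets, 2 with probe sets without a cross-hybridization suffix preferred, 11 with trended robust variances, 26 with array weights, 8 with the block for the 3 arrays, 11 with the array median as a covariate, and 4 to 7 when leaving out each array. Genes changed at 10 h numbered 70. After median centring 95 were called and after quantile normalization 100, and each of these sets held 66 of the 70. The count was 108 with trended robust variances, 127 with array weights, 110 with the block, 115 with the covariate, 30 without the 3 arrays, and 35 (without 10 h replicate 2) to 91 (without 2 h replicate 3) when leaving out each array. For 10 h against 2 h the 33 became 57, 62, 52, 60 and 12 in that order, and 12 to 42 when leaving out each array. Genes changed at any time, 56, became 88 with trended robust variances, 97 with array weights, 91 with the covariate, 18 without the 3 arrays, and 23 to 72. Shared calls, 4, became 1 with the mean of all probe sets, 2 with the suffix preference, 11, 19, 8 and 11 with trended variances, array weights, the block and the covariate, and 4 to 7. Early genes that rose further, 3, became 0 with the mean of all probe sets, 5 with trended variances and 8 with array weights, and 2 to 4. Late genes, 30, became 48 with trended variances, 19 at an adjusted p below 0.01, 46 with the block, 54 with the covariate, 9 without the 3 arrays, and 10 to 35. Lists that passed at 2 h, 2, became 1 after quantile normalization, 0 with an estimated correlation, 0 with directional fry, 4 without the 3 arrays, and 1 (without 0 h replicate 3) to 5 (without 0 h replicate 1, 2 h replicate 1 or 2 h replicate 2). Those at 10 h, 6, became 11 with each probe set tested, 0 with an estimated correlation, 0 and 10 with directional and mixed fry, 3 without the 3 arrays, and 4 to 8. Those for 10 h against 2 h, 8, became 5 with the suffix preference, 5 with the filter at the median gene, 0 with an estimated correlation, 0 and 4 with directional and mixed fry, and 6 to 8. No gene called as raised at 2 h fell back under any of these, and only the few genes called at 2 h could enter that count. The low counts without the 3 arrays come with fewer arrays. With the block for the 3 arrays the median moderated SD of a gene was 0.181, against 0.234 in the main fit. This smaller spread goes with the higher counts of the block. The main fit keeps the difference between the 3 arrays and the other 5 in its spread. For the remaining settings the cause was not tested.

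Some named genes changed sign with the suffix preference, where another probe set takes the gene's place. TSC22D3 then had −0.107 at 2 h, −0.163 at 10 h and −0.0562 for 10 h against 2 h, and at 10 h KLF2 had −0.22 and NFKBIA −0.39, all at an adjusted p of 1.00. The replacing probe sets of TSC22D3 and KLF2 had means of 4.45 and 4.42, below the highest negative control value of 4.73, so these sign changes are read at background; that of NFKBIA had 5.20. No other named call changed sign under any alternative. The share of raised calls at 10 h moved by under 10 points with the scalings tried.

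Replicate numbers are shared between the times. Same-numbered arrays did not deviate together: between 0 h and 2 h the correlations of their deviations across genes were 0.26, −0.14 and −0.06, and 2 of 8 arrays had their own number as the closest array of another time. The numbers were therefore not taken to pair the arrays. With a replicate block, 8 genes changed at 2 h, 67 at 10 h and 34 between them, 8 calls were shared, and 5 lists passed for 10 h against 2 h.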

Other observations

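The tests without shared list members below were set before their results were seen; the genes named in the next paragraph outside the naming rule were chosen after their values were seen.

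Several further genes rose after 10 h in limma; SOCS1, PIK3IP1, NFIL3, GSDME and DDIT4 are members of the glucocorticoid-induced list. The alternatives were not summarised for these genes one by one. SOCS1, a feedback inhibitor of cytokine signalling, rose by 2.59 (log2; adjusted p = 6.39e-05), CH25H, cholesterol 25-hydroxylase, by 2.54, and PIK3IP1, an inhibitor of PI3-kinase, by 2.38. NFIL3, a transcription factor that represses clock-controlled genes, rose by 1.97, GSDME, a pore-forming substrate of caspase 3, by 1.93, IL10 by 1.72 and JAK2 by 1.24. DDIT4, an inhibitor of mTORC1, rose by 1.20 and TP53INP1, a stress-induced nuclear protein, by 1.52. CH25H started at 2.91 and IL10 at 4.31, inside the range of the negative controls.

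The lists below did not pass camera at 10 h against 0 h, and called genes are those of limma over all genes. G2/M genes had 39 of 57 positive and none called (adjusted p = 0.0548), and T-lineage identity genes 23 of 43 positive and none called (adjusted p = 0.130), 1 when adjusted over the list alone. Of 25 p53 targets TP53INP1 was called (adjusted p = 0.297), of 34 amino acid stress genes DDIT4 (adjusted p = 0.483) and of 17 clock genes NFIL3 (adjusted p = 0.483). None was called among 27 caspase and apoptosis execution genes (adjusted p = 0.544), 42 genes of the citric acid cycle and oxidative phosphorylation (0.276), 24 of glycolysis and glucose uptake (0.306), 19 of cholesterol synthesis (0.492), 21 of the unfolded protein response (0.785), 17 of heat shock (0.785) or 14 replication histones (0.276). Markers of other cell types also held no called gene: 15 of B cells (0.866), 14 of myeloid cells (0.202), 11 of natural killer and cytotoxic cells (0.0999), 8 of erythroid cells (0.483) and 16 of epithelial and stromal cells (0.580). Adjusted over the list alone, 1 cholesterol gene was lowered, and none passed among the G2/M, caspase, citric acid cycle, glycolysis, unfolded protein response, heat shock and histone genes or the markers of other cell types. The median was negative while the mean and camera were positive for caspase, unfolded protein response, heat shock, p53 and clock genes, and for epithelial and stromal markers the median was positive and the mean negative.

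The rise of the interferon list at 10 h may rest on members it shares with the glucocorticoid-induced list. Without ISG20, the only shared gene, the other 28 still stood higher (unadjusted camera p = 9.08e-05, mean 0.20, median 0.10), which argues against that explanation, although the list's call was not kept with an estimated correlation (adjusted p = 0.907). For cell cycle inhibitors and quiescence genes the values that explanation needs were there: without the 6 shared genes, BTG1, KLF2, CDKN1A, CDKN1C, FOXO1 and FOXO3, the other 14 had an unadjusted camera p of 0.350, with a mean of 0.04 and a median of −0.02.

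Across all 19775 genes the log2 fold changes at 2 h and 10 h correlated at 0.48. Unchanged groups, simulated with untreated arrays used in both comparisons, gave 0.45 on average. The covariance was 0.0181 against a simulated 0.0198. Genes are not independent replicates, and these values concern all genes and not the called ones.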
